A study of Homo sapiens with 4 samples.

How the data were processed

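The material was human cells labelled HG3, a B cell line from chronic lymphocytic leukaemia, as an unedited control and as a METTL3 knockout. Each genotype had 1 RNA-seq library and 1 Ribo-seq library, prepared with the Illumina TruSeq Ribo Profiler kit per the labels' protocols. Samples were grouped by their titles into 4 groups of 1 library: control RNA-seq, METTL3 knockout RNA-seq, control Ribo-seq and METTL3 knockout Ribo-seq. Labels do not say whether the RNA-seq and Ribo-seq libraries of a genotype came from the same culture.

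Per the submitters' processing notes, Bowtie, HISAT2 and edgeR were used with the human build GRCh38 (hg38), with no roles or versions listed. How reads were counted per gene, how reads matching several genes were treated and which genes were kept are not given in the sources used here. The authors deposited a table of 12059 genes. Its 4 level columns are named as TPM in the file header, but the deposited signal in each is a whole number of reads multiplied by 1 factor per library, and the columns sum to between 1576164 and 16076254. The factors were 1.004825 for control RNA, 0.91123 for knockout RNA, 1.005523 for control footprints and 0.978629 for knockout footprints. Division by these factors gave whole reads, within a tolerance of 0.02 reads, for 99.99% of the values above 0 in control RNA and 100% in each of the other 3 columns. No division by gene length was seen. The deposited ratio columns hold translation efficiency, which is the footprint signal divided by the RNA signal of the same genotype. The deposited log2 column is the log2 of the knockout efficiency over the control efficiency, and 1194 of its cells hold spreadsheet error text where a library was at 0. The deposited p-value and q-value columns come from Fisher's exact test on the 4 rounded signals of a gene: the listed p lay within 1% of a recomputed one for 1000 of 1000 genes drawn at random. The authors' class column calls a gene UP or DOWN where q was under 0.05 and the log2 ratio beyond 1. That test compares the reads of these libraries, not the genotypes. In 14 rows a spreadsheet date stands in place of the gene name. Of the 12059 rows, 12001 matched a gene of the reference gene table by symbol or synonym, 11922 of them protein-coding. The table held 0 mitochondrially encoded genes.

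Recovered reads were scaled to CPM, counts per 1000000 reads of the library total in the table. Library totals were 15999056 reads for control RNA, 15887322 for knockout RNA, 3606558 for control footprints and 1610584 for knockout footprints. The choice between library totals and the deposited scaling was made after the column sums had been seen: the deposited footprint sums differ as much as the read totals do, with the knockout at 0.435 of the control. Reads rather than TPM were analysed because the columns turned out to be scaled reads. Changes are log2 ratios of knockout over control CPM with a prior count of 0.5 reads scaled to library size. The efficiency change is the footprint change minus the RNA change. Genes entered where the mean of the 2 Ribo-seq libraries and the mean of the 2 RNA-seq libraries each reached 20 reads, which left 8503 genes. A gene counted as higher or lower where its change was at least 2-fold, a rule of size and not a test. With 1 library per group there is no residual spread, so no model over both kinds of library could be fitted and no p-value was computed. The 95% intervals of single genes come from the reads (exact Poisson for levels, normal on the log2 scale for changes) and cover counting error only, since reads without molecular identifiers are not independent molecules. A fold against a library at 0 is given as "at least", computed with 3 reads in that library. It takes the reads of the other libraries as exact and the error of the 0 as Poisson. It is a lower bound only under these assumptions.

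The size rule, the floor, the gene lists and the rule for named genes were fixed before the data were examined. Named genes are METTL3, the measured m6A writers, erasers and readers, the 10 highest and 10 lowest efficiency changes, the 6 highest and 6 lowest footprint and RNA changes among the 4968 protein-coding genes with a mean of at least 100 reads in each assay, and in each list the 3 members with the largest efficiency change. Some genes that the rule names are not reported here. Genes named outside it are said to be so. The lists covered m6A enzymes and readers, 8 groups of splicing factors, 3′ end processing, ribosomal proteins, translation factors, mitochondrial ribosome, oxidative phosphorylation, proteasome, stress responses, B cell receptor pathway, B cell identity, antigen presentation, CLL driver genes, apoptosis, NF-kB, p53, MYC and interferon targets, cell cycle, DNA repair, cholesterol synthesis, glycolysis, chaperones, histones, short-lived immediate early transcripts, and markers of T and NK, myeloid, erythroid and platelet, stromal and epithelial, and plasma cells. For each list with at least 5 members past the floor (36 lists), the median change was placed as a percentile among 10000 random lists of the same size matched on mean expression in 10 bins. The percentile describes these libraries and is not a p-value. Intervals of list medians are order-statistic intervals over members.

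Alternatives were a prior count of 5 or 0.05, a floor of 100 reads or none, TMM scaling, median-centred ratios, the deposited scaling with a pseudocount of 1, a 1.5-fold rule, the authors' own thresholds, and for lists no matching, 20 bins or members of 1 list only. A scaling factor moves all genes of a library alike. Relative to library totals, TMM moved the median change by -0.15 for RNA, -0.11 for footprints and 0.04 for efficiency, median centring by -0.09, -0.03 and 0.08, and the deposited scaling by -0.15, -1.19 and -1.04. List percentiles do not depend on such a shift. Tested on simulated reads with Poisson noise and known efficiency changes, the rule recovered 47 of 50 genes at a log2 change of 1.5, 46 of 47 at -1.5, 50 of 50 at 2 and 47 of 47 at -2, and called 47 of 8291 unchanged genes (0.567%). In the same simulation a list of 30 genes, shifted by 0.5 on the log2 scale, reached a percentile of 100. Of 40 lists drawn at random from the simulated genes, which could hold changed genes, 4 fell outside the central 95%. The simulated reads held no spread beyond Poisson noise, so these rates need not hold for the real libraries. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the TMM factors alone. No reads, genome sequence, GC content or transcript lengths were analysed here.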

Results

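METTL3 is the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on messenger RNA. The series set METTL3 knockout cells against control cells of the line labelled HG3, a B cell line from chronic lymphocytic leukaemia (CLL), and its title places the comparison in the control of splicing factor abundance by m6A. RNA levels were measured by RNA-seq and ribosome occupancy by Ribo-seq, which sequences the mRNA fragments (footprints) that ribosomes shield from nuclease. There was 1 library per genotype and assay, so no difference below has a replicate check. The RNA-seq libraries held 15999056 reads (control) and 15887322 reads (knockout) over 12059 genes. The Ribo-seq libraries held 3606558 reads (control) and 1610584 reads (knockout), a 2.24-fold difference in depth. Knockout footprints were at 0 for 2298 genes and control footprints for 1342, against 390 and 558 in RNA. Values in brackets are 95% intervals and cover counting error only.

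METTL3 itself, on chromosome 14 at 21498138 to 21511340 of GRCh38, was lower in knockout footprints and, to a smaller extent, in knockout RNA. Its footprints went from 300 to 39 reads, or 83.2 CPM [74.0, 93.1] to 24.2 CPM [17.2, 33.1], which is 3.42-fold lower. Its RNA went from 1006 to 854 reads, or 62.9 CPM [59.1, 66.9] to 53.8 CPM [50.2, 57.5], a log2 change of -0.23 [-0.36, -0.09]. Its translation efficiency, the footprint level divided by the RNA level, was 2.92-fold lower, a log2 change of -1.55 [-2.05, -1.05]. In the authors' deposited table, its efficiency is 0.298 in the control and 0.049 in the knockout, a log2 ratio of -2.61 with a Fisher's exact q of 2.54e-32. RNA and footprints of METTL3 were thus still present in the knockout libraries, and which exon was edited is not given in the sources used here.

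Transcripts that define B cells had few or no reads in all 4 libraries, while transcripts of red cell precursors were abundant. The single genes in this paragraph and its figure were picked after their values were seen. PAX5 had 1 RNA read in the control and 5 in the knockout, CD79A 3 and 1, CD74 9 and 8, and MS4A1 and IGHM 0 and 0. Their footprints in control and knockout numbered 0 and 0 for PAX5, 1 and 3 for CD79A, 41 and 2 for CD74, 11 and 0 for MS4A1 and 39 and 5 for IGHM. An RNA count of 0 in the table does not show that a transcript was absent, since EEF1G, a translation elongation factor, had 0 RNA reads beside 700 and 395 footprints. In contrast, GATA1, the main erythroid transcription factor, had 4428 and 3891 RNA reads, KLF1 had 2034 and 2333, and ALAS2, the erythroid haem synthesis enzyme, 3049 and 3498. HBE1, embryonic epsilon globin, took 14292 CPM of control footprints and 15684 CPM of knockout footprints. The 30 measured members of the fixed B cell identity list had a median of 0.625 CPM in control RNA, where the median of all genes was 36.4 CPM, and 18 of them were under 1 CPM. The 8 measured members of the fixed erythroid and platelet list had medians of 19.2 CPM in control RNA and 112 CPM in control footprints. The sums of the lists gave another order than their medians: the erythroid list summed to 501 CPM of control RNA and 452 CPM of knockout RNA, and the B cell identity list to 729 and 745 CPM, of which TCF3, IKZF1 and MEF2C made up 83.6% and 80.6%. Of the other cell type lists, the stromal and epithelial list had a median of 22.6 CPM in control RNA, led by the keratins KRT8 and KRT18, the T and NK cell list 3.25 CPM, and the myeloid and plasma cell lists 0.125 CPM each. The 7 measured members of the myeloid list summed to 32.1 CPM in control RNA and 77.4 CPM in knockout RNA, and to 146 and 387 CPM in footprints. The libraries below are therefore called by their labels.

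**Figure D1:**
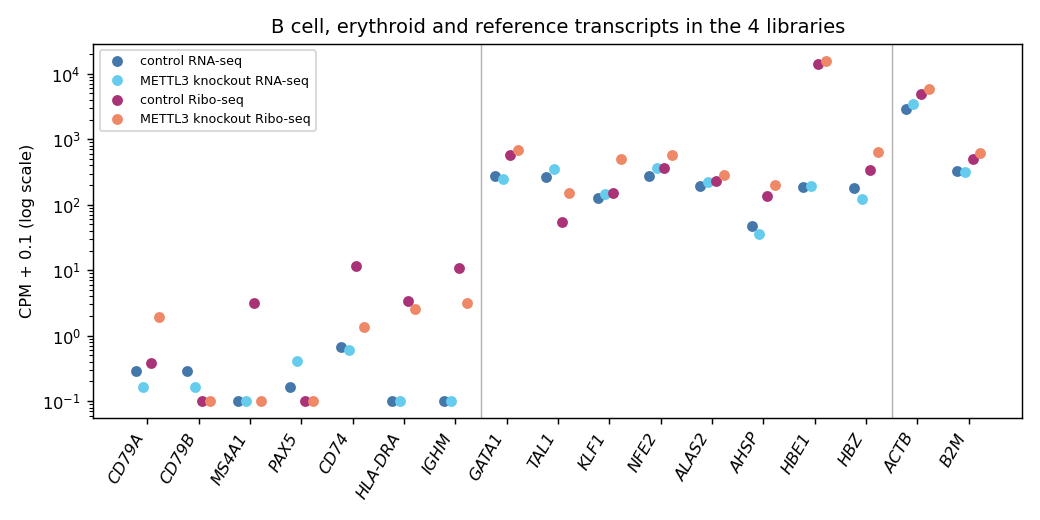
Level of 17 B cell, erythroid and reference transcripts in each of the 4 libraries, in CPM plus 0.1 on a log axis, 1 point per library and no error bars. Points on the lowest line are at 0 reads; the 7 B cell transcripts on the left lie at or below 11.4 CPM in every library, while HBE1 reaches 15684 CPM.

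RNA levels differed less between the libraries than footprints did, and far more genes were higher than lower in the knockout. Of 8503 genes, 328 were at least 2-fold higher and 29 at least 2-fold lower in knockout RNA (91.9% higher), against 218 and 57 (79.3% higher) with either TMM or the deposited scaling. The highest and lowest genes named next were ranked only among the 4968 protein-coding genes with a mean of at least 100 reads in each assay. The highest RNA changes were in TRANK1 (log2 2.5 [2.35, 2.66]), C15orf39 (2.46 [2.31, 2.61]), GRIN2D, an NMDA receptor subunit (2.07 [1.91, 2.23]), ECM1 (2.04 [1.91, 2.17]), KMT2D, a histone H3 lysine methyltransferase (2.03 [1.97, 2.08]), and the amino acid transporter SLC7A8 (1.73 [1.65, 1.82]). The lowest were ARG2, mitochondrial arginase (-1.63 [-1.84, -1.41]), HMGCS1 (-1.44 [-1.49, -1.40]), ACAT2 (-1.27 [-1.37, -1.17]), INSIG1 (-1.26 [-1.33, -1.2]), FAM178B (-1.26 [-1.41, -1.11]) and ALDOC (-1.26 [-1.37, -1.15]). HMGCS1, ACAT2 and INSIG1 belong to sterol synthesis and its feedback control.

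Sterol and energy metabolism transcripts were lower in knockout RNA as groups. Of 23 cholesterol synthesis genes, 6 were 2-fold lower and 0 were 2-fold higher, with a median of -0.66 [-0.94, -0.40], below all 10000 random lists. MSMO1, a sterol oxidase, was at -1.2 [-1.33, -1.07] in RNA and -2.43 [-2.93, -1.93] in footprints. The footprints of the group were lower too, with a median of -0.71 (percentile 0.13, or 6.35 with a floor of 100 reads), and its efficiency had a median of -0.03 (percentile 56.6). Within the group, efficiency was lower for SC5D (-1.52 [-2.20, -0.84]) and MSMO1 (-1.23 [-1.74, -0.71]). Glycolysis RNA had a median of -0.46 over 21 genes (percentile 0), with 2 genes 2-fold lower, and GAPDH was at -0.75 [-0.77, -0.73]. The efficiency median of glycolysis was 0.23 (percentile 94.2), or -0.82 with the deposited scaling, and 3 genes were 2-fold higher: SLC16A3 (1.78 [1.15, 2.42]), TPI1 (1.36 [1.22, 1.5]) and GAPDH (1.04 [0.96, 1.11]). Oxidative phosphorylation RNA had a median of -0.30 over 59 genes (percentile 0) with none past 2-fold, and its efficiency median was 0.04 (percentile 84.4), with NDUFC2 at -2.15 [-3.64, -0.66], NDUFS1 at -1.34 [-1.58, -1.10] and NDUFB8 at 1.31 [0.50, 2.11].

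Immune and interferon-related transcripts were higher in knockout RNA as groups. The B cell receptor pathway list had a median of 0.47 [0.18, 0.95] over the 16 of 27 measured members past the floor (percentile 99.6), with 2 members 2-fold higher. Its members past the floor are signalling genes such as INPP5D, SYK and DAPP1, with efficiency changes of 1.94 [0.51, 3.37], -1.72 [-2.66, -0.79] and -1.03 [-2.08, 0.01], while CD79A stood near 0 reads. INPP5D rested on 5 control footprints. The interferon list had a median of 0.52 [0.16, 1.14] over 13 genes (percentile 99.2). In it SAMD9 was at 2.59 [2.16, 3.02] in RNA and ISG15 at 1.14 [0.83, 1.44], and efficiency split both ways, with EIF2AK2, the kinase PKR, at -4.57 [-6.22, -2.92] on 3 knockout footprints, PARP9 at -2.29 [-3.53, -1.06], and ISG15 at 1.65 [1.22, 2.09]. Antigen presentation genes had a median of 0.96 over the 6 of 21 measured members past the floor (percentile 99.96) and a footprint median of 1.25 (percentile 99.1, or 54.6 without the floor). HLA-C was at 1.04 [0.46, 1.61] in RNA from 36 control reads, HLA-E at 0.89 [0.74, 1.04] and TAP1 at 1.45 [0.99, 1.91]. Without the floor the antigen presentation percentile turned to 1.81 in RNA and that of the B cell receptor list was 88.1, or 95.7 with a floor of 100 reads. NF-kB targets were at 0.44 in RNA (percentile 98.5, but 96.6 with a floor of 100 reads and 95.8 without the floor) and 0.90 in footprints (percentile 99.3) over 15 genes, with TNFAIP3 at 1.90 [1.07, 2.74], IER2 at 1.34 [1.17, 1.51] and REL at -1.67 [-2.37, -0.97] in efficiency. In footprints their direction turned with the deposited scaling, which gave -0.30. The summed RNA of the myeloid list was also higher in the knockout, at 32.1 CPM in the control and 77.4 CPM in the knockout. Most of it came from LYZ, at 30.8 and 67.3 CPM (493 and 1069 reads), and only 1 of the 7 measured members passed the floor.

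Footprint changes spread more widely than RNA changes, with an SD over genes of 1.40 on the log2 scale against 0.47. The footprint SD was 1.21 with genes at 0 placed at 3 reads and no prior count. The footprint libraries were also shallower than the RNA libraries, and how much of the spread this gives was not tested. In the knockout, 1339 genes were at least 2-fold higher and 1477 at least 2-fold lower in footprints (47.6% higher). With the deposited scaling, the split was 184 higher and 4795 lower (3.70% higher). Footprint extremes were ranked only among the 4968 protein-coding genes with a mean of at least 100 reads in each assay. The highest were CHMP6, an ESCRT-III subunit (26 to 185 reads, log2 3.96 [3.37, 4.55]), ZNHIT2 (3.30 [2.86, 3.74]), TRANK1 (3.18 [2.70, 3.66]), TPGS1 (3.10 [2.70, 3.50]), C4orf48 (3.01 [2.64, 3.38]) and ISG15 (2.79 [2.48, 3.10]). The lowest was ATP5MD, a small ATP synthase subunit, with 308 control reads and 0 knockout reads, at least 45.8-fold lower. It was followed by the mitochondrial ribosome subunit MRPS10 (427 to 3 reads, -5.85 [-7.49, -4.21]), GYPE (-5.40 [-7.41, -3.39]), MRPS18C (468 to 5 reads, -5.30 [-6.57, -4.03]), KRIT1 (-4.17 [-5.45, -2.90]) and CKS2, a subunit of cyclin-dependent kinases (-4.03 [-5.11, -2.95]). GYPE belongs to a family of similar genes, so its reads are uncertain. Genes without any knockout footprint were common at low RNA levels: among genes with 100 to 200 RNA reads, 26.3% had none, against 9.89% in control footprints thinned to the knockout total. At 400 to 800 RNA reads the shares were 5.23% and 0.864%.

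**Figure D2:**
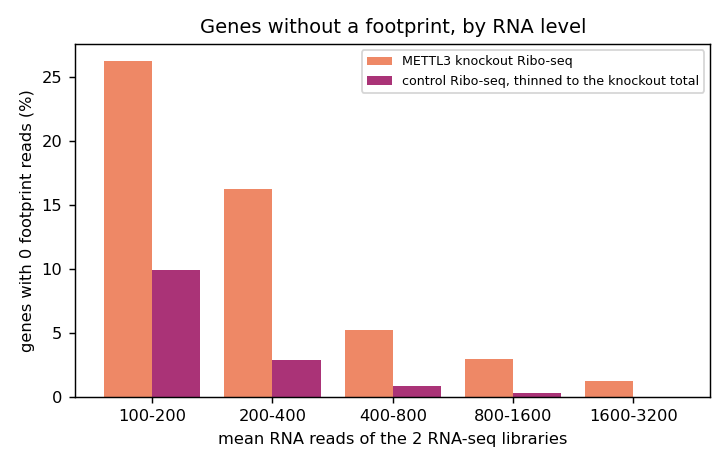
Share of genes with 0 footprint reads, in percent, by mean RNA reads of the 2 RNA-seq libraries, for knockout footprints (orange) and for control footprints thinned at random to the knockout total (purple). The share is higher in the knockout library at each RNA level, from 26.3% against 9.89% at 100 to 200 RNA reads to 1.2% against 0% at 1600 to 3200.

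Footprint changes followed RNA changes only in part. Across the 8503 genes, which are not independent replicates, Pearson's r was 0.406 and Spearman's rho 0.467, and r was 0.551 over the 1186 genes with a mean of at least 500 footprints. Of the genes 2-fold changed in RNA, 199 were 2-fold higher in both measures, 16 were 2-fold lower in both, 10 were higher in RNA and lower in footprints, and 0 were lower in RNA and higher in footprints. In KMT2D the measures went apart: its RNA was 4.08-fold higher, with 3245 control and 13133 knockout reads, while its footprint change was 0.01 [-0.21, 0.24].

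**Figure D3:**
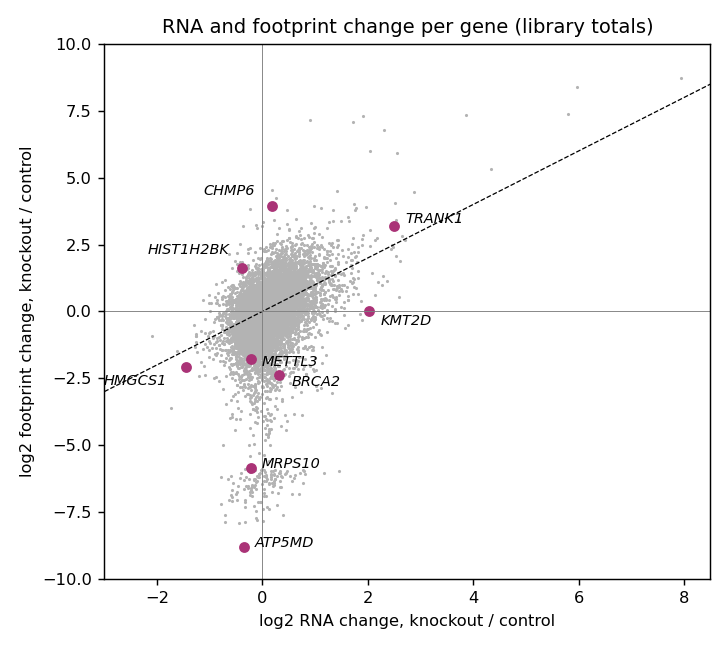
Log2 change (knockout over control, library totals) in RNA on the x axis and in footprints on the y axis, 1 point per gene past the floor, with named genes in purple, the line of equal change dashed, and genes at 0 reads placed by the prior count, which bounds no fold. Points below the dashed line have lower efficiency, as METTL3 at -1.55, and the deposited scaling would move all points down by a median of 1.19.

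Translation efficiency was lower for more genes than it was higher. With library totals, 810 genes were at least 2-fold higher and 1466 at least 2-fold lower in the knockout (35.6% higher), and 6227 lay within 2-fold. With the deposited scaling the split was 81 higher and 4738 lower (1.68% higher), and the authors' deposited table classes 225 genes as UP and 5794 as DOWN. Of the 4760 DOWN genes past the floor, 1466 were 2-fold lower with library totals and 216 had an efficiency change above 0, while 78 of 78 UP genes past the floor were 2-fold higher. The median deposited efficiency was 0.199 in the control and 0.088 in the knockout. The deposited scaling moves the efficiency changes by a median of -1.04, so genes and lists between 0 and about that size with library totals lie below 0 with it. With genes at 0 placed at 3 reads and no prior count for any gene, 825 were higher and 1476 lower. A prior count of 0.05 gave 827 and 1474, so the move from the main counts is not due to the genes at 0 alone. Calls were more frequent at low depth: 46.1% of genes with 20 to 50 footprints were called, and 9.36% of those with at least 500, where 51 were higher and 60 lower.

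The lowest efficiencies in the knockout were in ATP5MD (at least 36.1-fold lower), MRPS10 (log2 -5.64 [-7.28, -4.0]), MRPS18C (-5.24 [-6.52, -3.95]), GYPE (-5.17 [-7.18, -3.16]), KRIT1 (-4.08 [-5.36, -2.79]), ARMT1 (-3.75 [-4.49, -3.02]), CKS2 (-3.60 [-4.70, -2.51]), ADAMTS3 (-3.36 [-4.54, -2.18]), the small GTPase RAB18 (-3.30 [-4.28, -2.33]) and the splicing kinase CLK1 (-3.27 [-4.30, -2.24]). Each of these 10 genes had at most 16 knockout footprints. They and the 10 highest were ranked only among the 4968 protein-coding genes with a mean of at least 100 reads in each assay. The highest were in CHMP6 (3.78 [3.14, 4.42]), the ribosomal protein gene RPL29 (2.46 [2.15, 2.76]), C9orf40 (2.38 [1.92, 2.85]), ZNHIT2 (2.38 [1.87, 2.88]), C4orf48 (2.32 [1.77, 2.87]), FRAT2 (2.27 [1.81, 2.73]), NENF (2.20 [1.82, 2.57]), the inducible heat shock gene HSPA1A (2.05 [1.85, 2.24]), NGRN (2.04 [1.71, 2.37]) and the histone gene HIST1H2BK (2.01 [1.90, 2.13]). RPL29, HSPA1A and HIST1H2BK have near-identical copies or pseudogenes, so their reads may be split.

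The median efficiency change of the m6A writers lay low among random lists, with an interval over members that includes 0. It was -0.90 [-1.53, 0.40] over 12 genes (percentile 0.37), with 0 genes 2-fold higher and 5 lower: METTL16 (-1.82 [-2.34, -1.29]), METTL3, METTL5 (-1.53 [-1.85, -1.21]), CBLL1 (-1.34 [-1.75, -0.92]) and RBM15B (-1.03 [-1.96, -0.09]). METTL3, the edited gene, counts among the 12, and no value without it is given here. METTL14, the partner of METTL3, was at -0.93 [-1.39, -0.46] in efficiency and 0.38 [0.25, 0.52] in RNA. VIRMA was at -0.87 [-1.09, -0.65], ZCCHC4 at -0.69 [-1.38, 0.00] and ZC3H13 at -0.12 [-0.44, 0.21]. RBM15 (0.84 [0.66, 1.03]), PCIF1 (0.82 [0.29, 1.34]) and WTAP (0.40 [0.17, 0.63]) lay above 0 with library totals and below 0 with the deposited scaling, at -0.21, -0.22 and -0.65. No writer changed 2-fold in RNA.

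Erasers and readers of m6A had a median efficiency change of -0.40 [-0.82, 0.34] over 16 genes (percentile 4.50), with 1 gene 2-fold higher and 3 lower. FMR1 (-2.11 [-2.86, -1.35]), YTHDC2 (-1.42 [-1.86, -0.98]) and YTHDF3 (-1.19 [-1.52, -0.87]) were lower, and IGF2BP2 was higher (1.47 [1.06, 1.87]). YTHDF1 and YTHDF2 were at -0.64 [-0.98, -0.30] and -0.76 [-0.95, -0.57]. The demethylase genes ALKBH5 (0.71 [0.01, 1.41]) and FTO (0.35 [-0.07, 0.78]) and the reader IGF2BP1 (0.34 [0.21, 0.48]) were above 0 with library totals and below 0 with the deposited scaling. PRRC2A RNA was at 0.89 [0.85, 0.93] with an efficiency change of -0.49 [-0.61, -0.37]. HNRNPA2B1, ELAVL1, RBMX, HNRNPC, IGF2BP3 and YTHDC1 lay at -0.81, -0.82, -0.31, -0.27, -0.15 and 0.18.

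Splicing factors, the group named in the series title, lay within the central 95% of random lists as 1 group in efficiency, footprints and RNA. Over the 191 members of 8 splicing lists the median was -0.15 [-0.25, -0.04], against -0.06 for matched random lists (percentile 3.31), with 5 genes 2-fold higher, 25 lower and 161 within 2-fold. Their RNA median was -0.10 (percentile 5.57), with 2 genes higher and 0 lower, and their footprint median -0.18 (percentile 6.09). SF3B1, the U2 snRNP subunit recurrently mutated in CLL, on chromosome 2 at 197389784 to 197435093 of GRCh38, went from 2612 to 468 footprints and had an efficiency change of -1.04 [-1.19, -0.89]. None of the 8 lists alone lay outside the central 95% of random lists in efficiency. In RNA, 3 lists moved outside it without matching on expression: SR proteins (0.60), hnRNPs (0.07) and U1 and Sm (1.18). The exon junction list did so with a floor of 100 reads (98.0).

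Single members of these lists changed 2-fold in both directions in efficiency, more of them down than up. This skew is not particular to splicing factors, since 810 of all 8503 genes were higher and 1466 lower. Of 24 SR protein genes 2 were higher and 4 lower (median -0.24, percentile 9.14), with SRSF8 at 1.27 [0.98, 1.55], SRSF2 at 1.17 [1.05, 1.29] and TRA2B at -1.23 [-1.42, -1.04]. Of 25 hnRNP genes 0 were higher and 2 lower (-0.14, percentile 21.2), with PTBP2 at -2.18 [-3.23, -1.13], HNRNPA1, which has many pseudogenes, at -1.02 [-1.33, -0.71] and HNRNPDL at -0.89 [-1.02, -0.76]. In the U2 and SF3 list 0 of 23 were higher and 2 lower (-0.29, percentile 6.51), with SMNDC1 at -1.72 [-2.15, -1.30], SF3B1, and SF3B5 at 0.79 [0.61, 0.97]. In the U1 and Sm list 3 of 14 were lower (0.15, percentile 85.2): SNRPG, with 74 control and 0 knockout footprints (at least 7.91-fold lower), TIAL1 (-2.63 [-3.19, -2.07]) and TIA1 (-1.55 [-1.93, -1.18]). In the U5 and tri-snRNP list 1 of 24 was higher and 4 lower (0.09, percentile 82.1), with LSM6 at -3.86 [-5.32, -2.40], LSM5 at -2.72 [-3.29, -2.16] and PPIH at -1.87 [-2.31, -1.44].

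The remaining splicing lists, and the list of 3′ end processing and export, also held more members 2-fold lower than higher in efficiency, as did all genes past the floor. In the Prp19 and catalytic list 1 of 30 was higher and 4 lower (-0.15, percentile 30.5), with PRPF18 at 62 control and 0 knockout footprints (at least 8.04-fold lower), PLRG1 at -1.79 [-2.15, -1.43] and PRPF4B at -1.44 [-1.75, -1.13]. Its RNA median, -0.14, lay at percentile 0.85. In the exon junction and nonsense-mediated decay list 1 of 19 was higher and 2 lower (-0.04, percentile 54.7), with UPF3A at 1.14 [0.61, 1.68] and MAGOHB at -2.18 [-2.81, -1.56]. Of 32 other splicing regulators 0 were higher and 4 lower (-0.15, percentile 23.0), among them CLK1, RBM4 (-1.68 [-2.16, -1.2]) and RBFOX2 (-1.29 [-2.19, -0.39]). In 3′ end processing and export 1 of 30 was higher and 2 lower (-0.34, percentile 2.85): PABPN1 (1.0 [0.70, 1.31]), which turned to -0.05 with the deposited scaling, PCF11 (-1.25 [-1.58, -0.91]) and CPSF3 (-1.07 [-1.33, -0.81]).

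**Figure D4:**
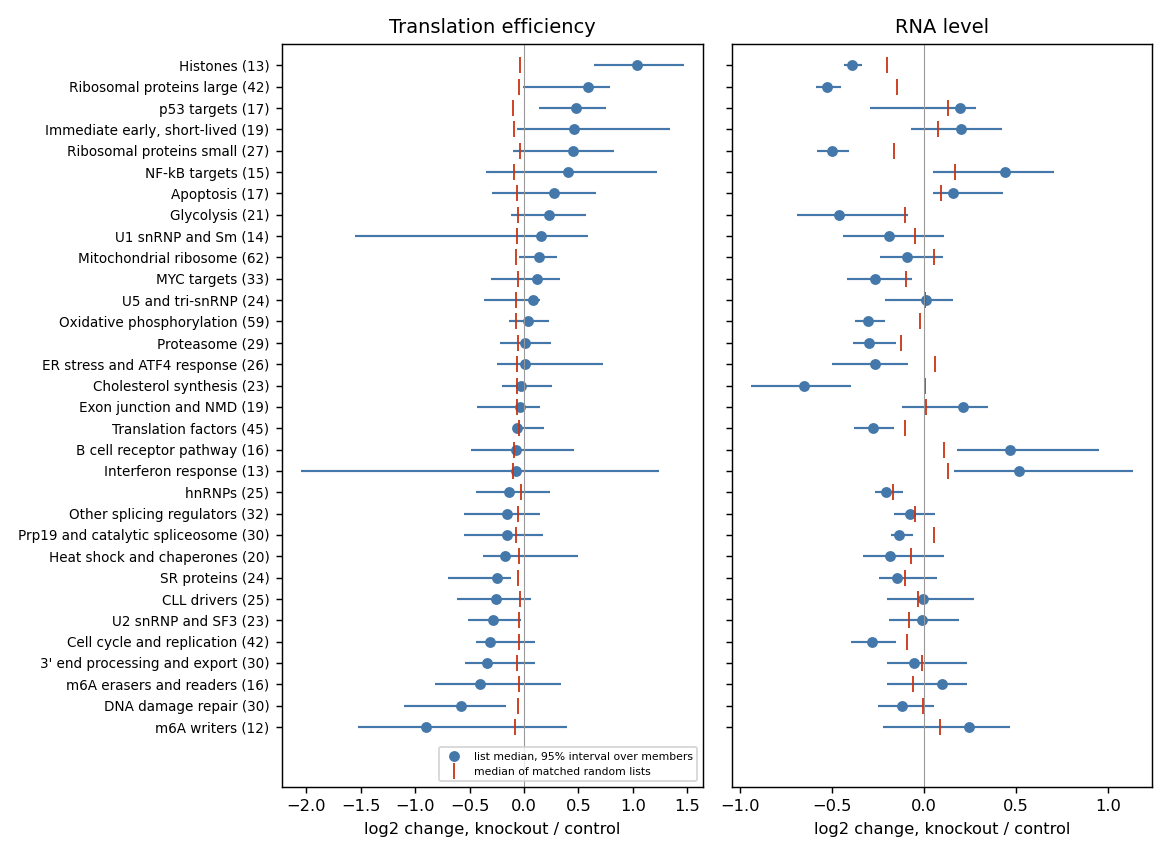
Median log2 change (knockout over control, library totals) of each fixed gene list with at least 12 members past the floor, in efficiency on the left and RNA on the right, with member numbers in brackets, 95% intervals over members as lines and the median of matched random lists as red ticks. Histones have the highest efficiency median (1.04, or -0.01 with the deposited scaling) and m6A writers the lowest (-0.90).

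Histone and ribosomal protein genes had higher efficiency in the knockout with library totals, and the medians turned below 0 with the deposited scaling. Of 13 histone genes 7 were 2-fold higher and 0 lower in efficiency, with a median of 1.04 [0.64, 1.47] (percentile 100), or -0.01 with the deposited scaling. HIST1H2BK, HIST2H2BE (1.48 [1.33, 1.64]) and HIST1H1E (1.47 [1.40, 1.53]) led the group, whose RNA median was -0.40 (percentile 3.35) and footprint median 0.61. Large subunit ribosomal protein genes had an efficiency median of 0.59 [-0.01, 0.79] over 42 genes (percentile 100), or -0.46 with the deposited scaling, with 9 higher and 3 lower, and small subunit genes 0.45 [-0.10, 0.82] over 27 genes (percentile 99.99), or -0.60, with 5 higher and 2 lower. Their RNA medians were -0.53 [-0.59, -0.45] and -0.50 [-0.58, -0.41], each below all 10000 random lists, while their footprint medians were -0.003 and -0.08, with 2 higher and 6 lower in the large and 0 higher and 3 lower in the small subunit. Their higher efficiency thus goes with lower RNA and not with more footprints. The members went apart: RPL29, RPL7 (1.89 [1.38, 2.41]) and RPS2 (1.39 [1.10, 1.68]) were higher, and RPL23A (-3.25 [-4.04, -2.45]), RPS27A (-3.15 [-4.06, -2.24]) and RPS12 (-1.38 [-1.68, -1.08]) lower. Ribosomal protein genes have many processed pseudogenes, and RPL7 had 60 control footprints beside 11558 RNA reads, so reads shared with copies may set these values.

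The lists of translation factors, mitochondrial ribosome, proteasome and MYC targets lay below the central 95% of random lists in RNA and within it in efficiency. Translation factors had an RNA median of -0.28 (percentile 0.29) and an efficiency median of -0.07 (percentile 44.7) over 45 genes, with 0 higher and 4 lower, among them EIF4EBP2 (-2.42 [-3.63, -1.22]), EIF1 (-1.32 [-1.46, -1.17]) and the release factor ETF1 (-1.22 [-1.48, -0.96]). Mitochondrial ribosome genes had an RNA median of -0.10 (percentile 0.57) and an efficiency median of 0.14 (percentile 96.6), or -0.91 with the deposited scaling, over 62 genes, with 5 higher and 6 lower, including MRPS10, MRPS18C and MRPS33 (-1.66 [-2.10, -1.22]). Proteasome genes had an RNA median of -0.30 (percentile 1.29) and an efficiency median of 0.01 (percentile 68.4) over 29 genes, with PSMA6 at -1.24 [-1.59, -0.88], PSMB10 at -1.19 [-2.09, -0.30] and PSMD8 at 0.94 [0.81, 1.07]. MYC targets had an RNA median of -0.27 (percentile 1.40, or 2.66 with 20 bins) and an efficiency median of 0.12 (percentile 90.1) over 33 genes, with PPAN at 2.26 [1.37, 3.14], NOP58 at -1.28 [-1.49, -1.06] and RRP9 at 0.97 [0.64, 1.30]. Chaperones had an efficiency median of -0.17 over 20 genes (percentile 23.1), with CHORDC1 at 162 control and 0 knockout footprints (at least 19.1-fold lower), HSPA14 at -2.12 [-2.59, -1.65] and HSPA1A higher.

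DNA repair and cell cycle genes were lower in efficiency and in footprints. Of 30 DNA repair genes 10 were 2-fold lower and 0 higher in efficiency, with a median of -0.58 [-1.11, -0.17] (percentile 0.06), and 13 were 2-fold lower in footprints. BRCA2, a mediator of homologous recombination, went from 318 to 27 footprints while its RNA went from 2146 to 2652 reads, an efficiency change of -2.70 [-3.27, -2.12]. The checkpoint kinase ATR was at -2.13 [-2.66, -1.60] and RAD50 at -1.58 [-1.93, -1.24]. Of 42 cell cycle and replication genes 5 were 2-fold lower and 0 higher in efficiency (median -0.31, percentile 1.02, or 6.87 without matching on expression), 11 were 2-fold lower in footprints (-0.54, percentile 0.18), and the RNA median was -0.29 (percentile 0.14). The lowest were CCNE2 (-2.28 [-3.33, -1.22]), E2F1 (-1.99 [-3.34, -0.63], 36 to 5 footprints) and RFC3 (-1.56 [-1.97, -1.15]).

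Stress, p53 and immediate early genes contained members at both extremes. The ER stress and ATF4 list had an RNA median of -0.27 (percentile 0) and an efficiency median of 0.01 (percentile 65.1) over 26 genes, with 4 higher and 2 lower. ATF4, the transcription factor of the integrated stress response, had 64 control and 0 knockout footprints (at least 7.69-fold lower in efficiency) beside 4853 and 3889 RNA reads. ATF3 had 79 and 0 footprints (at least 7.79-fold lower), and DDIT4 was at 1.62 [1.44, 1.80]. Targets of p53 had an efficiency median of 0.48 [0.14, 0.76] over 17 genes (percentile 98.8), or -0.54 with the deposited scaling, and percentile 92.2 with a floor of 100 reads or 95.1 with members of 1 list only, with 4 higher and 2 lower, among them TP53I3 (1.94 [1.10, 2.77]), BTG2 (1.73 [1.30, 2.17]) and SESN1 (-1.91 [-3.16, -0.66]). Immediate early transcripts had a median of 0.46 over 19 genes (percentile 98.9), or -0.58 with the deposited scaling, with 6 higher and 2 lower, the latter ATF3 and NR4A1 (-2.49 [-3.78, -1.19]). Apoptosis genes had a median of 0.27 over 17 genes (percentile 92.3), or -0.77 with the deposited scaling, with 3 higher and 0 lower: BAD (1.82 [1.12, 2.53]), APAF1 (1.05 [0.60, 1.49]) and BID (1.04 [0.78, 1.30]).

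CLL driver and lineage lists were small or mixed in efficiency. CLL driver genes had a median of -0.26 over 25 genes (percentile 9.35), with 2 higher and 3 lower, among them NFKBIE (1.28 [0.74, 1.82]), RPS15 (1.19 [1.04, 1.33]) and SF3B1. The 5 B cell identity members past the floor had a median of -0.27 (percentile 32.7), with LEF1 at -1.88 [-2.72, -1.04], CD37 at -0.28 [-1.06, 0.50], and TCF3 at 1.04 [0.69, 1.40]. The 5 erythroid members past the floor had a median of 0.39 (percentile 89.1), or -0.66 with the deposited scaling, with AHSP at 0.95 [0.70, 1.21] and HBG1, whose reads overlap those of HBG2, at 0.86 [0.58, 1.14]. The 6 stromal and epithelial members past the floor had a median of 0.83 [0.32, 1.18] (percentile 99.4), or -0.22 with the deposited scaling, and an RNA median of -0.61 (percentile 0.01), with COL1A2 at 1.18 [0.32, 2.04], KRT8 at 1.0 [0.84, 1.17] and EPCAM at 0.89 [0.58, 1.2]. Too few members of the T and NK (2), myeloid (1) and plasma cell (1) lists passed the floor for a median. Of these, PRF1 was at 1.21 [0.89, 1.52], CD3D at -1.10 [-1.80, -0.40], LYZ at -0.87 [-1.19, -0.55] and XBP1 at 0.76 [0.47, 1.05]. Of the 36 lists, 6 lay above and 3 below the central 95% of random lists in efficiency, 4 and 3 in footprints, and 4 and 13 in RNA, where random lists would place 1.8 outside in each. In simulated reads, 4 of 40 lists drawn at random, which could hold changed genes, fell outside, a larger share.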

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

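No paired analysis was possible because the result comes from no test and each group holds 1 library, and for the same reason no library could be left out. The authors' thresholds could be applied only to efficiency, since their table holds no test of RNA or footprints. The values of METTL3 under TMM, a prior count of 5 and the deposited scaling were added after the data were seen. With a floor of 100 reads, genes higher and lower numbered 328 and 564 in efficiency, 565 and 704 in footprints and 91 and 17 in RNA, over 4985 genes. Without a floor they numbered 1476 and 3198, 2084 and 2732, and 1302 and 177, over 11820 genes. A 1.5-fold rule gave 1758 and 2438, 2408 and 2409, and 1164 and 243. These 3 settings change how many genes are tested or how large a change is counted. The deposited scaling gave 81 and 4738 in efficiency, 184 and 4795 in footprints and 218 and 57 in RNA, through its shift of all genes. TMM also gave 218 and 57 in RNA. On the authors' log2 ratio, 225 and 5794 genes passed q under 0.05, 152 and 5484 passed q under 0.01, and 241 and 5854 passed p under 0.05. All other counts under prior counts of 5 and 0.05, TMM and median centring stayed within 1.5 times. The correlation of footprint with RNA changes was 0.526 with a floor of 100 reads, 0.242 without a floor and 0.453 with a prior count of 5. METTL3 was at -2.57 in efficiency, -2.95 in footprints and -0.38 in RNA with the deposited scaling, and at -0.38 in RNA with TMM, all in the main direction.

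The numbers of lists outside the central 95% of random lists stayed between 7 and 10 for efficiency (9 in the main setting), 5 and 7 for footprints (7) and 14 and 23 for RNA (17). Antigen presentation reversed in RNA without a floor, at percentile 1.81, where 13 of its 21 members were under 1 CPM in control RNA, and its footprint percentile was 54.6. Calls of lists that ended under a setting were the B cell receptor pathway in RNA (95.7 with a floor of 100 reads, 88.1 without a floor), NF-kB targets in RNA (96.6 and 95.8), p53 targets in efficiency (92.2 with a floor of 100 reads, 95.1 with members of 1 list only), cell cycle in efficiency (6.87 without matching), cholesterol synthesis in footprints (6.35 with a floor of 100 reads), histones in footprints (95.7 without matching) and MYC targets in RNA (2.66 with 20 bins), and the causes were not tested. Other calls were gained. Without matching, these were SR proteins (0.60), hnRNPs (0.07), U1 and Sm (1.18), DNA repair (0.79), chaperones (0.41) and histones (0.01) in RNA. Histones also gained one without a floor (0.92), as did antigen presentation in efficiency (99.4). The exon junction list gained one in RNA with a floor of 100 reads (98.0). With the deposited scaling, 29 of the 66 named genes above 0 in efficiency turned below 0. Of these, 5 had been 2-fold higher, and went to -0.047 for PABPN1, -0.0020 for TCF3, -0.0098 for BID, -0.013 for GAPDH and -0.046 for KRT8. It took 27 other named genes below the 2-fold rule. In the other direction, it took 16 past the rule on the lower side, among them METTL14 (-1.96). Of 144 named genes in efficiency, 139 kept their side of the rule with TMM, 135 with median centring, 138 with a prior count of 5 and 144 with a prior count of 0.05. Placing libraries at 0 at 3 reads, with no prior count for any gene, moved no list median of efficiency by more than 0.01. The largest move, 0.008 in the B cell receptor list, came from the prior count, since 0 of its 16 members had a library at 0. Efficiency changes spread more widely at low depth, with an SD over genes of 2.09 at 20 to 50 footprints and 0.59 at 500 or more, and the cause was not tested. Poisson noise alone called 47 of 8291 unchanged genes in simulated reads, over all depths.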

Other observations

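All tests and groups of genes in this part, apart from the fixed lists, were chosen after the values were seen. CEBPE, HDC, CLC and EVI2B, genes known from granulocytes, had at most 8 RNA reads in the control and at least 122 in the knockout. CEBPE, a transcription factor of late granulocyte development, had 1 control and 366 knockout RNA reads, a log2 change of 7.94 [5.11, 10.77], and 0 and 132 footprints. HDC, the histamine-forming enzyme of basophils and mast cells, had 5 and 303 RNA reads (5.80 [4.52, 7.07]) and 0 and 51 footprints, CLC, the Charcot-Leyden crystal protein of eosinophils and basophils, 8 and 122 RNA reads (3.86 [2.83, 4.89]) and 0 and 50 footprints, and EVI2B 8 and 171 RNA reads (4.34 [3.32, 5.37]). TCN1, a granule protein of neutrophils, was at 2.87 [2.30, 3.44]. LYZ, lysozyme, was present in both, at 493 and 1069 RNA reads (1.13 [0.97, 1.28]) and 296 and 158 footprints. The erythroid factors GATA1 and KLF1 stood at 277 and 127 CPM in control RNA and 245 and 147 CPM in knockout RNA. With 1 library per genotype, a difference between the genotypes and a difference between cultures or clones were not tested here.

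The globin genes HBG1, HBG2 and HBE1 had more footprints than RNA reads, and HBZ had fewer. HBZ had 2880 and 1955 RNA reads in control and knockout beside 1221 and 1015 footprints. HBB had 3 and 0 RNA reads beside 0 and 8 footprints. The RNA of HBE1, at 185 CPM in the control, lay above the all-gene median of 36.4 CPM. HBG2 had 10 and 18 RNA reads in control and knockout beside 11512 and 6977 footprints, HBG1 211 and 220 beside 4802 and 4081, and HBE1 2963 and 3112 beside 51544 and 25260. HBG1 and HBG2 are near-identical copies, so their reads depend on how shared reads were counted in each assay. PRAME, a tumour antigen, had 27127 and 35351 RNA reads, and the RNA-binding protein gene LIN28B 4058 and 3347.

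The first pattern weighed is the high level of erythroid transcripts beside B cell transcripts near 0 in libraries labelled as a B cell line. A small share of other cells mixed into cultures of that line would leave its own transcripts abundant. The B cell identity list had a median of 0.625 CPM in control RNA, against 36.4 CPM over all genes. In control footprints it was 0.832 CPM, against 24.7 CPM. These low medians are part of the pattern itself, so they speak only against a small share. Cultures made up almost wholly of other cells would give the same values, and that stays open. A change of identity caused by the knockout is argued against by the control library, since the summed erythroid list in knockout RNA was 0.902 of that in the control. Whether the libraries come from cells with an erythroid program stays open. The erythroid list's median was 30.7 times that of the B cell identity list in control RNA, but this ratio restates the pattern and adds no support. It does not single out an erythroid program either, since the erythroid median, 19.2 CPM, lay below that of all genes and below the 22.6 CPM of the stromal and epithelial list. In control footprints the erythroid median was 112 CPM, against 20 CPM for the stromal and epithelial list. A set of 8 erythroid genes, GATA1 and KLF1 among them, had medians of 183 CPM in control RNA and 171 CPM in knockout RNA, far above all genes, but it was chosen after its values were seen and so decides nothing. Whether the cells, the libraries or the table columns were exchanged stays open, and no genotype check of the line was possible with gene counts.

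The second pattern is the number of genes without a knockout footprint, 2298 genes, of which 135 were past the floor. Lower depth alone is argued against, because control footprints thinned to the knockout total left 1506 genes at 0 on average and 1534 at most in 100 draws. For the 135 genes past the floor, loss of the transcripts is argued against as well: their median RNA change was -0.03 [-0.12, 0.05]. The floor asks for RNA reads, and the RNA changes of the other genes at 0 were not examined. For those genes it stays open. Few distinct molecules sequenced many times stay open. The knockout library had 0.989 genes with 1 to 3 reads for each gene with 10 to 12 reads, against 1.79 to 2.30 in the thinned control, but that range holds no spread between libraries and does not decide it. A loss of translation of particular genes in the knockout was not tested and stays open, and GC content was not analysed here.

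The third pattern is the lower efficiency of most genes in the authors' deposited table. With the deposited scaling 91.5% of genes past the floor had lower efficiency in the knockout and the median change was -1.12, while library totals gave a median of -0.0785. The ratio of knockout to control factors in the table was 0.907 for RNA, where TMM on the same reads gives 0.908, and 0.973 for footprints, where TMM gives 2.08. A footprint scaling that left the depth difference in place and a general fall in translation could each give lower values for most genes. They cannot be told apart here, because library totals centre the data by construction and no external standard was analysed.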
